A study of Zea mays with 16 samples.

How the data were processed

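RNA of maize (Zea mays) kernels was measured on 16 2-colour arrays, 4 for each of 4 recombinant inbred lines, RIL60 and RIL78 (tolerant) and RIL66 and RIL68 (susceptible). Per the labels' protocols, plants grew in the field in 2 randomised blocks per treatment, soil moisture was held near 30% or near 16% from 3 weeks before flowering, and each RNA came from a pool of 6 to 9 kernels from 3 ears taken 10 days after pollination. Each array compared stressed with well watered kernels of a line, with dyes swapped between arrays. The dye of channel 1 in each file header matched the label on all 16 arrays.

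Per the file headers, the authors scanned the slides with a ScanArray instrument whose software deposited a linear intensity and a local background for each spot and channel, not background subtracted. Every value lay between 0 and the scanner maximum of 65535. Each array has 2048 spots: 1000 probes with 2 spots each and 48 spots treated as controls, which are absent from the value table. A mark set by the authors excluded 106 probe spots over the 16 arrays. The authors also deposited a table of log2 ratios with 2000 rows per array, whose processing is not given in the sources used here. Its rows carry no probe name and were matched to spots by slide position and sorted probe name, a match borne out by correlations per array of 0.88 to 0.99 with the ratios computed here. This places the direction at stress over well watered and the centring near 0, with medians from -0.000722 to 0.00144. Its scale stays partly unknown, since its slope on the ratios computed here over bright probes ran from 0.41 to 0.96. These values were used as an alternative.

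Intensities were corrected with limma's normexp (offset 50) and normalised within each array by loess with controls and excluded spots at weight 0. Excluded spots were left out, the 2 spots of a probe were averaged, and signs were turned by the dyes in the labels to give stress over well watered. Within-array normalisation assumes that most probes do not change, so a shift of all probes cannot be seen. A spot was above background when it exceeded it by 2 background SDs. The precision depends on the number of arrays and on signal over background. Median background ran from 232 to 1299 in Cy5 and from 306 to 2273 in Cy3, and the correlation between duplicate spots from 0.23 to 0.84. Loess ratios and Aquantile-scaled mean intensities gave levels per channel.

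All tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment and a threshold of 0.05. Changes per line and differences between lines of a class came from 1 fit to the 16 arrays with a coefficient per line and a dye term. The common response and the difference between classes were tested on 1 mean per line. SEs are those of the moderated fit. Overlaps were tested with Fisher's exact test. Figures were drawn with matplotlib 3.10.9. On simulated data with 200 of 1000 probes changed, a log2 change of 1 was recovered for 98% of probes in RIL60, 100% in RIL78, 98% in RIL66 and 98% in RIL68, for 86% in RIL60 minus RIL78, 94% in RIL66 minus RIL68, 100% in the common response and 74% in tolerant minus susceptible. A change of 0.5 was recovered for 56%, 72%, 72%, 58%, 28%, 26%, 86% and 8% in the same order. In the real data these comparisons called between 0 and 75 of 1000 probes, and fewer calls make the adjusted threshold stricter. These shares are therefore likely too high for the real data, and 0 calls do not show that no probe changed.

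The comparisons, tests and most alternatives were fixed before the data were examined. Alternatives covered background correction, normalisation, the deposited values, a filter on dim probes, the excluded spots, the direction of RIL66, the dye term, blocks, array weights, the threshold and each array or line left out. The rule for named probes took the largest rises and falls past the threshold with one sign on all 4 arrays of a line. For the common response it took the largest moderated statistics of one sign in all 4 lines, and for the classes the largest with no overlap. For differences between lines it took the largest per direction. It also asked for a gene name, a condition that no probe meets: none of the 1000 probe IDs was found among the 49888 rows of the gene table used here. That condition was dropped and the first 2 per direction are named. For the same reason none of the 22 gene lists prepared beforehand could be matched to a probe, and tests of gene lists were not run.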

Results

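Kernels of 4 maize recombinant inbred lines, collected 10 days after pollination in the field, were compared between water stress and full irrigation. RIL60 and RIL78 are described by the submitters as drought tolerant, and RIL66 and RIL68 as susceptible. Recombinant inbred lines are fixed lines bred by repeated selfing from a cross, so each line stands for 1 genotype. Each line was measured on 4 arrays, and every array held poly(A) RNA of stressed kernels and of well watered kernels of the same line in different dyes. The stress sample carried Cy5 on 2 arrays of each line and Cy3 on the other 2. Between 30.3% and 76.3% of the probe spots on an array lay above the local background in at least 1 channel, which together with the number of arrays limits the precision. The highest correlation between any 2 arrays was 0.72, so no array was a copy of another. The 4 arrays of a line are hybridisation replicates, and the labels do not say whether they came from separate extracts, so p-values within a line measure the spread between hybridisations, which may be technical. The files do not pair the probe IDs with genes, so the results are given by probe ID.

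In RIL60, probes a116pe0973 and a116pe0872 rose under water stress. Probe a116pe0973 was 2.96-fold higher, a log2 ratio of 1.57 ± 0.11 (SD, n = 4 arrays; adjusted p = 1.36e-05). Probe a116pe0872 was 2.72-fold higher, at 1.44 ± 0.45 (adjusted p = 5.95e-05). Among the probes called, the largest fall was that of a116pe0012, at -1.74 ± 0.24 (adjusted p = 0.0442), followed by a116pe0829 at -0.82 ± 0.32 (adjusted p = 0.00126). All 4 probes had the same sign on each of the 4 arrays. Over all 1000 probes, limma called 29 changed, 22 higher and 7 lower, with a median size of 0.72 on the log2 scale. The count was 13, 12, 13 and 15 without replicate 1, 2, 3 and 4 of the line, and a116pe0012 passed in none of these 4 fits (adjusted p between 0.122 and 0.238), nor with the spread of the arrays scaled (0.383). The fit shares its spread over the lines: without replicate 2 of RIL68, where this probe lay far from the rest of that line, the same fall had an adjusted p of 1.71e-07, and without replicate 1, 3 or 4 of RIL78 or replicate 2 or 3 of RIL66 it lay between 0.0503 and 0.0596. Its value stayed between -1.83 and -1.62 without an array of RIL60 and was -1.88 with scaling. The deposited values gave -1.64, which passed (limma's adjusted p = 4.95e-09). They are blank for this probe on replicate 2 of RIL68, so that fit also lacks the array that lay far from the rest. Without background correction a116pe0872 was at 0.76 and a116pe0829 at -0.38. With the deposited values the split was 39 higher and 21 lower.

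In RIL78 75 probes changed, more than in any other line in this fit and in 27 of 32 other settings. Probe a116pe0746 was 8.61-fold lower under stress, at -3.11 ± 1.08 (SD, n = 4 arrays; adjusted p = 3.48e-07), and its stress channel was above background on 1 of the 4 arrays against 4 of 4 for the well watered channel. Probe a116pe0765 was 3.86-fold lower, at -1.95 ± 0.38 (adjusted p = 3.48e-07), with its stress channel above background on 2 of the 4 arrays. The largest rises among the probes called were those of a116pe0174, 2.74-fold at 1.46 ± 0.32 (adjusted p = 0.00192), and a116pe0970, 2.69-fold at 1.43 ± 0.90 (adjusted p = 0.000163). Of the 75 probes, 42 were higher and 33 lower, and 63 had one sign on all 4 arrays. The count was 43, 35 and 20 without replicate 1, 3 and 4 of the line. The sizes depended on the background: without background correction a116pe0746 was at -1.74, a116pe0765 at -1.05 and a116pe0174 at 0.80. The order of the lines turned with array weights (69 in RIL78, 100 in RIL60), with each line on its own arrays (39 and 66) and without replicate 4 of RIL78 (20, against 25 in RIL60 and 25 in RIL66). It also turned with the spread of the arrays scaled (35, against 43 in RIL66) and at 2-fold or more (7, against 9 in RIL60 and 10 in RIL66).

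**Figure D1:**
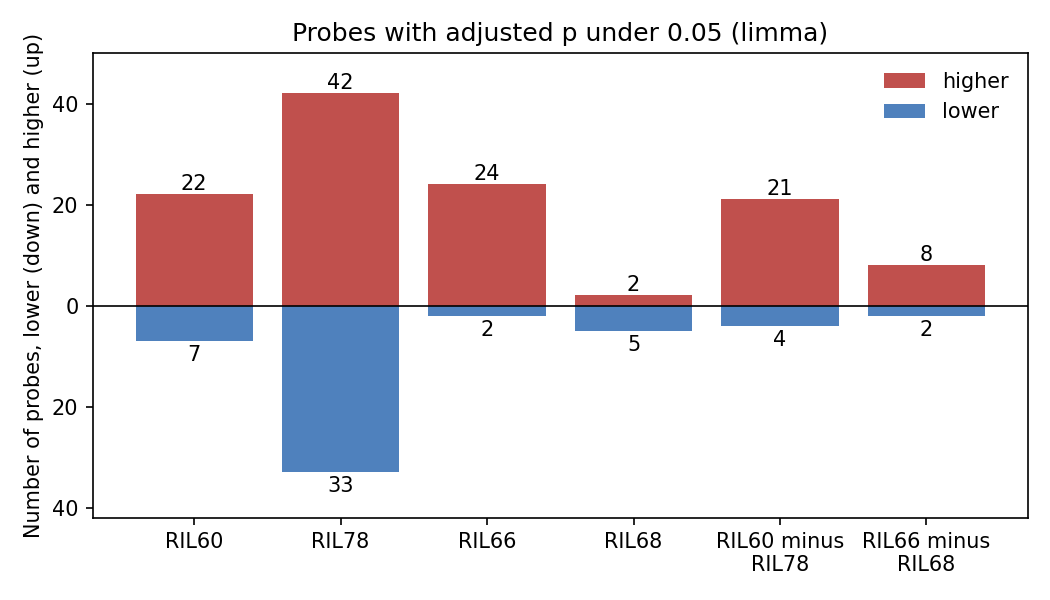
Number of probes with an adjusted p under 0.05 in each line (stress over well watered) and in the 2 differences between lines of a class; bars above 0 count higher probes and bars below 0 lower probes. RIL78 has 42 higher and 33 lower probes and RIL68 has 2 and 5.

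In RIL66, a susceptible line, probes a116pe0026 and a116pe0012 rose far more than the rest. Probe a116pe0026 was 45.2-fold higher under stress, at 5.50 ± 0.87 on the log2 scale (SD, n = 4 arrays; adjusted p = 3.80e-07). Probe a116pe0012 was 25.5-fold higher, at 4.67 ± 0.19 (adjusted p = 9.78e-07). For both probes the well watered channel was above background on 3 of the 4 arrays and the stress channel on all 4, and without background correction the values were 4.06 and 3.87, so the folds depend on that step. The falls that passed were small, a116pe0267 at -0.48 ± 0.21 (adjusted p = 0.0336) and a116pe0756 at -0.47 ± 0.12 (adjusted p = 0.0142), and both missed the threshold with median centring in place of loess (adjusted p = 0.0630 and 0.0710). Probe a116pe0267 also missed it without replicate 2, 3 or 4, and a116pe0756, at -0.25 without background correction, missed it without replicate 1, 2 or 4. Of the 26 probes called, 24 were higher and 2 lower. The count was 16 without replicate 2 and 12 without replicate 4. The split was 33 higher and 10 lower when the spread of the arrays was scaled, and 35 and 33 with the deposited values.

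RIL68 had the smallest number of changed probes, here and in all 32 other settings. On average 48.4% of the spots on its arrays were above background in at least 1 channel, the lowest mean of the 4 lines. The mean correlation between duplicate spots was also lowest there, at 0.396. Probes with an unadjusted limma p under 0.05 numbered 126 in RIL68, against 115 in RIL60, 142 in RIL66 and 212 in RIL78. The smallest count therefore does not show that this line responded least. Probe a116pe0973, which also rose in RIL60, was 2.12-fold higher, at 1.08 ± 0.20 (SD, n = 4 arrays; adjusted p = 0.00282), and a116pe0945 stood at 0.92 ± 0.42 (adjusted p = 0.0405). Probe a116pe0599 fell by 0.80 on the log2 scale (SD 0.12, adjusted p = 0.00282) and a116pe0565 fell by 0.97 (SD 0.81, adjusted p = 0.0136). Probe a116pe0945 missed the threshold without any one of the 4 arrays of the line (adjusted p between 0.0601 and 0.180), although its value stayed between 0.82 and 1.00, and with median centring (0.0815). It also missed without replicate 1, 2 or 4 of RIL60 or replicate 1 or 4 of RIL78 (adjusted p between 0.0552 and 0.0659). Probe a116pe0565 missed it without replicate 1 or 3, with no background correction, with plain subtraction and with the deposited values (adjusted p = 0.0605, 0.0587 and 0.0502 for these last 3, where its value was -0.40, -0.47 and -0.47). Probes a116pe0973, a116pe0945 and a116pe0599 were at 0.62, 0.49 and -0.48 without background correction. In all 7 probes were called, 2 higher and 5 lower. The count was 3 without replicate 1 or 3 of the line, without replicate 1, 2 or 4 of RIL60, and without replicate 1 of RIL78. The split was 2 higher and 10 lower with median centring, and 2 and 3 with the deposited values.

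**Figure D2:**
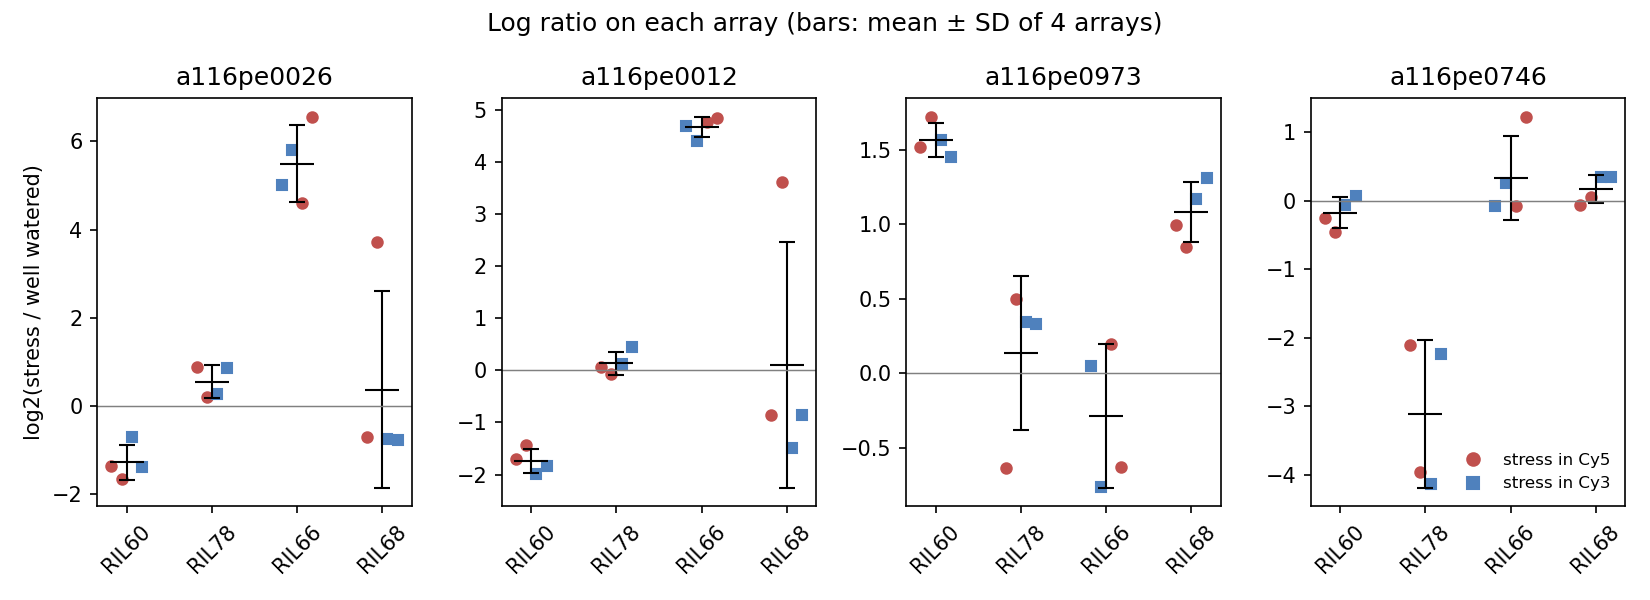
Log2 ratio of stress over well watered for 4 probes on each array; circles are arrays with the stress sample in Cy5 and squares those with it in Cy3, and bars give the mean ± SD of the 4 arrays of a line. Probe a116pe0026 lies near 5.50 in RIL66, and on replicate 2 of RIL68 it reads 3.71 where the other 3 arrays lie between -0.77 and -0.71.

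Whether the 4 lines shared a response was tested on 1 mean per line, since the line is the biological unit. No probe passed: limma called 0 of 1000, with a smallest adjusted p of 0.551, while 90 probes had an unadjusted p under 0.05 against 50 expected by chance. The probes nearest to a common rise were a116pe0872, at a mean of 0.80 (SE 0.17, n = 4 lines, higher in 4 of 4), and a116pe0533 at 0.47 (SE 0.11, 4 of 4). Those nearest to a common fall were a116pe0288 at -0.41 (SE 0.09, lower in 4 of 4) and a116pe0119 at -0.32 (SE 0.09, 4 of 4); all 4 had an adjusted p of 0.551. Without background correction these means were 0.39, 0.27, -0.16 and -0.12. The sign of a116pe0533 followed the dye. It was above 0 on every array with stress in Cy3. With stress in Cy5 it was below 0 except on replicate 4 of RIL66, at 0.92. Its rise in 4 of 4 lines thus appears only after averaging over the dye orientations. In RIL68 the well watered signal of a116pe0872 was not well above background on any array, and its ratio there, 0.29 ± 0.32 (SD), did not pass (limma's adjusted p = 0.578). One sign in all 4 lines was found for 189 probes, where 125 are expected if the lines had no direction in common. With the spread between hybridisations as the only error, the mean of the 4 lines differed from 0 for 62 probes, 36 higher and 26 lower. This speaks only for the RNA hybridised from these 4 lines, since arrays of a line may share an extract.

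The series set tolerant against susceptible lines. With 2 lines in each class no probe passed: limma called 0 of 1000, with a smallest adjusted p of 0.818, and 55 probes had an unadjusted p under 0.05 against 50 expected by chance. The largest moderated statistics with no overlap of the classes were those of a116pe0920, where the response was higher by 0.72 in the tolerant lines (SE 0.17), and a116pe0877, higher by 0.70 (SE 0.18). Probe a116pe0905 was at -0.82 (SE 0.19) and a116pe0896 at -0.70 (SE 0.17), both tolerant minus susceptible. All 4 had an adjusted p of 0.818. In the tolerant lines a116pe0877 followed the dye. It lay between 0.84 and 1.38 with stress in Cy5 and between -0.48 and -0.02 with stress in Cy3. The susceptible arrays with stress in Cy3 lay between -1.06 and 0.23, so the classes overlapped in that orientation. In RIL78 a116pe0920 was at 0.85 and 1.24 in Cy5 and at -0.22 and -0.21 in Cy3. Its tolerant arrays still lay above its susceptible arrays within each orientation. Signals of a116pe0905 were below background in both conditions on every array of RIL78 and of RIL66, on 4 of 4 stress channels of RIL60 and on 4 of 4 well watered channels of RIL68. For a116pe0896 this held for the stress channels of RIL78 and the well watered channels of RIL68, which leaves only bounds there. Without background correction a116pe0920, a116pe0877, a116pe0905 and a116pe0896 were at 0.47, 0.25, -0.17 and -0.24. The classes did not overlap for 354 probes, where chance gives 333. With lines as fixed effects, 15 probes differed between the 2 pairs of lines, 9 higher and 6 lower in the tolerant pair. These calls too were set against the spread between hybridisations only. Leaving out RIL60 gave 2 calls and leaving out RIL78 gave 1, in fits where the lone tolerant line is assumed to vary like the susceptible lines. No day recorded in the file headers held arrays of both classes; with the day as a random block over the 16 arrays 4 probes passed.

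The lines of a class differed from each other. Within the tolerant class, a116pe0746 differed by 2.94 between RIL60 and RIL78 (SE 0.38, adjusted p = 0.000105), with means of -0.17 and -3.11. In RIL60 its signal was above background on 2 of 4 arrays under stress and on 1 of 4 well watered, which leaves little room to measure a fall there. Probe a116pe0765 differed by 1.92 (SE 0.24, adjusted p = 0.000105), with means of -0.03 and -1.95. In RIL60 its signal was above background on 4 of 4 arrays well watered and on 2 of 4 under stress. Its well watered level there was 9.19 on the log2 scale, near the 9.16 that it had in RIL78 under stress. Room for a fall in RIL60 was therefore also small. In the other direction a116pe0174 stood at -0.70 in RIL60 and 1.46 in RIL78, a difference of -2.16 (SE 0.37, adjusted p = 0.00168). Probe a116pe0028 differed by -0.96 (SE 0.22, adjusted p = 0.0200) and lost its call without any replicate of RIL60, or replicate 3 or 4 of RIL78, and with the spread of the arrays scaled (adjusted p = 0.0613). In all 25 probes differed, 21 with the higher value in RIL60 and 4 in RIL78. The count was 22, of which 19 were among the 25, with the day in the file headers as a block, a fit equal to that within the 1 day that held both lines (3 arrays of RIL60 and 4 of RIL78). The differences of the 4 probes were 1.64, 1.06, -1.07 and -0.62 without background correction. It was 15, 16 and 14 without replicate 1, 2 and 3 of RIL60, and 16 without replicate 4 of RIL78.

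Within the susceptible class, a116pe0026 differed by 5.13 between RIL66 and RIL68 (SE 0.68, adjusted p = 0.000389) and a116pe0012 by 4.57 (SE 0.64, adjusted p = 0.000426). Their RIL68 means of 0.37 ± 2.23 and 0.11 ± 2.36 (SD, n = 4 arrays) hold replicate 2, which read 3.71 and 3.62 where the other 3 arrays were below 0; without that array the differences were 6.25 and 5.72. Probe a116pe0973 was lower in RIL66, at -1.37 (SE 0.25, adjusted p = 0.00461), and a116pe0267 stood at -0.80 (SE 0.17, adjusted p = 0.0189). In all 10 probes differed, 8 higher and 2 lower in RIL66. With the day as a block 2 probes differed, a116pe0026 and a116pe0012, and within the day that held 1 array of RIL66 and 3 of RIL68 it was 9, of which 3 were among the 10. In both fits the difference rests on that lone array of RIL66, so they say little about lost calls; a116pe0973 and a116pe0267 did not pass in them, at -1.63 and -1.07. Within the day the lone array is assumed to vary like those of RIL68. The differences of these 2 probes over all arrays were -0.72 and -0.52 without background correction. Probe a116pe0267 missed the threshold with median centring (adjusted p = 0.282) and without replicate 4 of RIL66 or replicate 1 or 3 of RIL68. The count was 21 without replicate 1 and 18 without replicate 3 of RIL66. The split was 13 higher and 12 lower with the spread of arrays scaled, and 11 and 15 with the deposited values; with that scaling a116pe0026 and a116pe0012 kept 4.46 and 3.91 but missed the threshold (adjusted p = 0.0767 and 0.132).

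Few probes were called in more than 1 line. Of 121 probes called in at least 1 line, 106 were called in 1 line, 14 in 2, 1 in 3 and 0 in all 4. Probe a116pe0973 rose in RIL60 and RIL68, and a116pe0872 in RIL60 and RIL78, while a116pe0012 fell in RIL60 and rose in RIL66. RIL60 and RIL66 shared 4 probes of one sign where independent lists give 0.542 (two-sided Fisher's exact test on calls of either sign, adjusted over 6 pairs, p = 0.00370), and 1 probe went opposite ways. RIL60 and RIL68 shared 2 where 0.079 are expected (Fisher's exact test, adjusted p = 0.0468). Of these 2, a116pe0945 missed the threshold in RIL68 when any 1 array of that line was left out. The other 4 pairs did not pass, with adjusted p from Fisher's exact test between 0.182 and 1. All lists came from 1 fit that shares the spread and the dye term of each probe over the lines. They are therefore not independent, and the expected counts and p-values of Fisher's test may overstate the overlap. In total 13 probes were called with one sign in at least 2 lines, and 7 without replicate 1, 2 or 4 of RIL60. Across probes, which are not independent replicates, the responses of 2 lines correlated weakly: Pearson's r ran from -0.16 (RIL60 and RIL66, Spearman's rho -0.03) to 0.17 (RIL78 and RIL68, rho 0.18), with a mean of 0.09 over the 6 pairs. These values were unstable: without a116pe0012 and a116pe0026 the lowest, RIL60 and RIL66, was 0.02. RIL78 and RIL68 gave 0.08 without replicate 2 of RIL78 and 0.24 without its replicate 1. RIL60 and RIL78 gave 0.06 without replicate 2 of RIL78, from 0.16, and RIL60 and RIL68 gave 0.07 without replicate 1 of RIL68, from 0.15. RIL66 and RIL68 gave -0.03 without replicate 2 and 0.28 without replicate 1 of RIL68, from 0.13. With the deposited values RIL60 and RIL68 gave 0.35 and RIL66 and RIL68 -0.10. RIL66 and RIL68 gave 0.26 with median centring, RIL78 and RIL68 gave 0.35 without dim probes, and RIL60 and RIL66 gave -0.29 without background correction.

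Arrays of a line agreed mostly when the dyes ran the same way. The mean r over pairs of RIL60 arrays was 0.58 for the same orientation and 0.06 for opposite orientations, and in RIL78 it was 0.53 and 0.00336. RIL68 gave 0.26 and 0.04. In RIL66 the values were 0.38 and 0.46, of which a116pe0012 and a116pe0026 carried part: without these 2 probes they were 0.17 and 0.27. The dye term passed for 109 probes, 56 higher and 53 lower in Cy5.

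**Figure D3:**
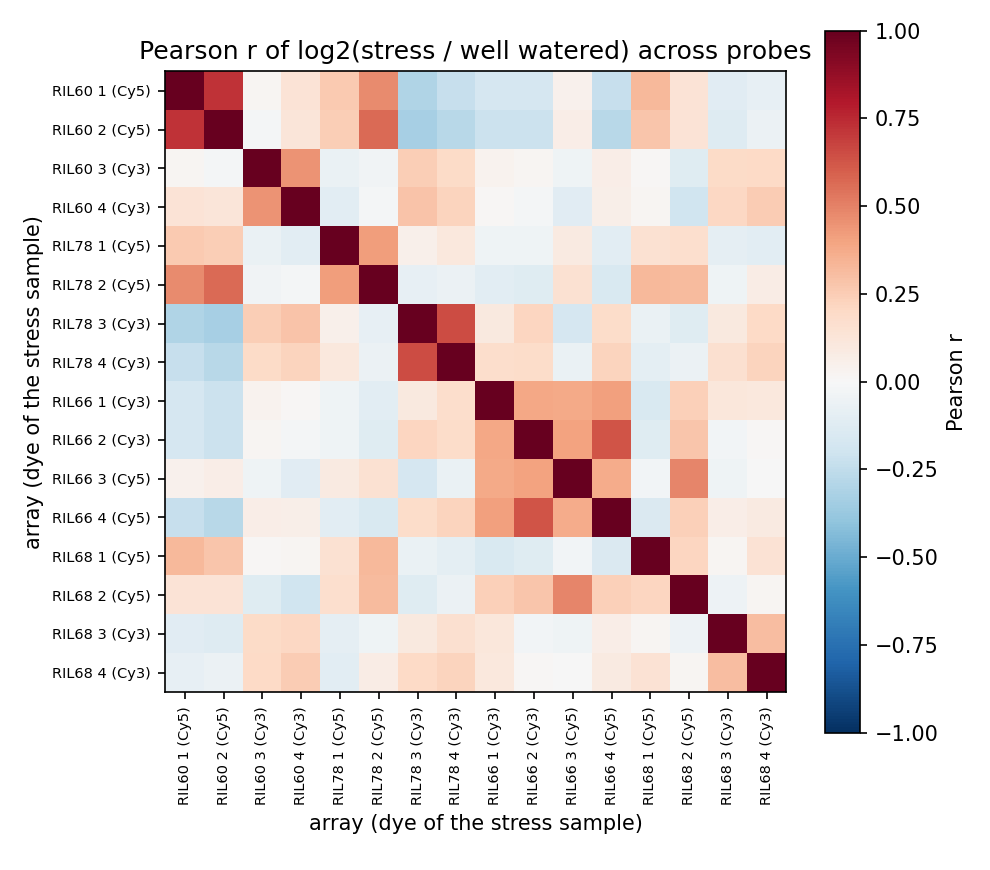
Pearson correlation across probes between every 2 of the 16 arrays, in log2 ratio of stress over well watered; the dye of the stress sample is in brackets and colour runs from blue (-1) through white (0) to red (1). Red blocks along the diagonal join arrays of one orientation in RIL60 and RIL78, with a highest r of 0.72, and all 4 arrays in RIL66, where a116pe0012 and a116pe0026 carry part of it.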

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

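The tests of explanations in this part were chosen after the results were seen, while the relabellings and splits of arrays were planned. On replicate 2 of RIL68, a116pe0012 read 3.62 and a116pe0026 read 3.71, where the other 3 arrays of the line lay between -1.49 and -0.85 and between -0.77 and -0.71. The deposited table leaves these 4 bright spots blank. A damaged spot is argued against by the duplicate spots, which differed by at most 0.16. RNA of RIL66 in place of RIL68 on this array is argued against by 9 other probes that part RIL66 from the other RIL68 arrays. On a scale from 0 (RIL68) to 1 (RIL66) this array had a mean position of 0.192. The RIL66 arrays lay at 0.833 to 1.18 (SD 0.180) and the other RIL68 arrays at -0.0891 to 0.0551. The probes were chosen and the scale set on these comparison arrays, so their line means are 1 and 0 by construction. An array kept out of that choice would tend to lie further in, by an amount that was not measured. The argument is therefore weaker than the gap implies. Across all probes replicate 2 of RIL68 correlated with RIL66 arrays at 0.24 to 0.49 and with its own line at -0.05 to 0.21. Without the 2 probes these values were -0.07 to 0.18 and 0.00658 to 0.37. A first test, over 22 other probes called higher in RIL66, had not settled this: the median was 0.19 on this array and 0.54 to 1.34 on the RIL66 arrays (SD 0.38). A smaller share of RIL66 RNA, a different kernel pool and the day, which no other array shares, stay open and untested, and no biological explanation was tested.

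The rise of a116pe0026 and a116pe0012 in RIL66 was weighed against dye and processing. A dye bias alone would give means of opposite sign in the dye orientations. These probes were named for one sign on all 4 arrays, so that outcome could not occur and its absence decides nothing. The means with stress in Cy3 and in Cy5 differed little next to their size. They were 4.55 and 4.80 for a116pe0012, and 5.41 and 5.58 for a116pe0026. Loess or normexp as the whole cause is argued against by net intensities with median centring alone, which kept at least 0.579 of the log2 value on every array. Net intensities still have the background subtracted, so they cannot judge background correction as such. Without any background correction the rises were smaller but remained, as given for RIL66 above. A difference between the kernel pools and a response of this line both stay open and cannot be parted with 1 line.

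Arrays of RIL60, RIL78 and RIL68 resembled each other mainly within a dye orientation. Their dye estimates correlated across probes with r between 0.350 and 0.642. A shared dye bias of single probes may therefore account for part of this in RIL60 and RIL78. With the dye of the other lines removed, r between the orientations rose from 0.062 to 0.296 in RIL60. In RIL78 it rose from 0.009 to 0.211. In RIL68 it did not rise, at 0.038 before and 0.029 after, so a shared bias is not shown to account for the pattern there. In RIL66 it fell from 0.673 to 0.367. The dye estimate of RIL66 correlated with those of RIL60, RIL78 and RIL68 at 0.068 to 0.155, below every r of dye estimates among those lines. In RIL66, however, the arrays with stress in Cy3 and those with stress in Cy5 share no day. Its dye estimate therefore also holds any effect of the day. The low r thus cannot decide whether RIL66 has the same bias. The slope of this estimate on the mean of the others was 0.101 (SE 0.024). Noise in that mean lowers the slope of any line below 1, so the slope alone does not decide this. Why RIL66 departs was not tested.

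Further single arrays lay apart from the other 3 of their line. Probe a116pe0973 read -0.63 on replicate 1 of RIL78, a116pe0288 read -0.72 on replicate 4 of RIL66, a116pe0877 read -1.06 on replicate 3 of RIL68, and a116pe0896 read 1.09 on replicate 4 of RIL68. On replicate 3 of RIL60, 49.7% of spots were above background against 72.6% to 76.0% on the other 3. In all 7 of 100 groups of 4 arrays held such an array, and chance gives about 5.

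The responses of 2 lines of a class differed by a test of the difference itself. Between RIL60 and RIL78 this held for 25 probes, among them a116pe0746 (2.94), a116pe0765 (1.92), a116pe0174 (-2.16) and a116pe0028 (-0.96). Of 35 splits of the 8 arrays, 1, the real one, gave as many, and the highest other gave 3, so a chance split of the hybridisations can be excluded. Arrays of a line may share an extract, so a chance difference between kernel pools cannot be excluded by these splits. Between RIL66 and RIL68 it held for 10 probes, among them a116pe0026 (5.13), a116pe0012 (4.57), a116pe0973 (-1.37) and a116pe0267 (-0.80). Again 1 of 35 splits gave as many, and the highest other gave 4, with the same limit; with the day as a block, where RIL66 has 1 array on the shared day, 2 probes differed. Within a line 8 relabellings of stress and well watered are too few for a share under 0.05: the real counts were 29, 75, 26 and 7, and the highest other was 1 in each of the 4 lines. For the common response the 8 sign flips are also too few, with 0 calls in the real data and at most 0 in the others.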

How the results depend on the processing

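The alternatives were chosen before the data were examined, except a dye term per line, the day as a random block for the common and class responses, the fits within a day, leaving out 2 probes from correlations, and leaving out arrays for named probes. The cause of a change was not tested unless the setting itself gives it. Counts of changed probes in RIL60, 29, became 58 with no background correction, 56 with plain subtraction, 19 with median centring, 60 with the deposited values, 17 with no dye term, 100 with array weights, 66 on its own arrays and 9 at 2-fold or more. RIL78, 75, became 43 with median centring, 35 with scaling, 121 with deposited values, 42 with no dye term, 39 on its own arrays and 7 at 2-fold. RIL66, 26, became 43 with scaling, 68 with deposited values, 11 on its own arrays and 10 at 2-fold. RIL68, 7, became 4 with no background correction, 12 with median centring, 19 with scaling, 16 without dim probes (507 probes were left), 2 with no dye term, 16 with array weights, 4 on its own arrays and 1 at 2-fold. RIL60 minus RIL78, 25, became 41 with deposited values, 38 with array weights and 14 at 2-fold. RIL66 minus RIL68, 10, became 21 with no background correction, 20 with subtraction, 25 with scaling, 26 with deposited values, 26 without dim probes and 2 with the day as a block. Probes of one sign in at least 2 lines, 13, became 27 with deposited values, 21 with array weights and 2 at 2-fold. The common response, 0, became 62 with lines as fixed effects, 11 with the day and 1 with the line as a random block, and tolerant minus susceptible, 0, became 15 with fixed effects and 4 with the day as a random block, all by treating arrays as replicates. A dye term per line allows a different dye effect in RIL66. It gave 34, 104, 31 and 10 in RIL60, RIL78, RIL66 and RIL68, 31 and 14 for the 2 differences and 18 for the overlap.

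With RIL66 turned in sign, its 26 calls became 2 higher and 24 lower, a116pe0026 -5.50, a116pe0012 -4.67, a116pe0267 0.48 and a116pe0756 0.47, and RIL66 minus RIL68 had 13 calls, with a116pe0026 at -5.87, a116pe0012 at -4.78, a116pe0267 at 0.16 and a116pe0973 at -0.80 (adjusted p = 0.102). In no other setting did a named value change sign; 52 of 612 values of called named probes under alternatives missed the threshold. Sizes were less stable: with no background correction 16 of the 24 called values shrank by over 1.5 times, and 4 moved as far with plain subtraction and 4 with the deposited values. Every probe named for the common and class responses shrank as far with no background correction.

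Leaving out each array gave 12 to 35 probes in RIL60, 20 to 93 in RIL78, 12 to 36 in RIL66, 3 to 8 in RIL68, 14 to 35 for RIL60 minus RIL78, 7 to 21 for RIL66 minus RIL68, 7 to 15 in at least 2 lines, 0 for the common response and, with lines left out too, 0 to 2 for tolerant minus susceptible.

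The replicate numbers were not taken to pair arrays of different lines: 10 of 24 same-numbered pairs had a correlation of deviations above 0.1, against 21 of 72 pairs of different number, with means of 0.014 and -0.00475, and 7 of 16 arrays correlated best with their own number, where chance gives 4. With the replicate number as a block the counts were 28, 79, 31 and 4 in RIL60, RIL78, RIL66 and RIL68, 23 and 11 for the 2 differences, 14 for the overlap, and, as contrasts of the 16-array fit, 60 for the common response and 18 for the classes.

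The mean correlation between lines, 0.09, stayed between 0.06 and 0.14 under these settings, arrays left out included. Leaving out every flagged spot was not run, since the files hold a single mark, and gene list tests were not run. Signal over background limits the rest: 68 to 128 probes per line were below background in both conditions on all 4 arrays.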

Other observations

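Channel levels of a116pe0026 and a116pe0012, scaled between arrays, varied between lines in both conditions. The well watered level of a116pe0026 was 9.02 ± 0.94 in RIL66 (log2, SD, n = 4 arrays), against 14.13 ± 0.21 in RIL60, 13.60 ± 0.51 in RIL78 and 12.62 ± 1.04 in RIL68. Its stress level was 14.52 ± 0.22 in RIL66, against 12.85 ± 0.59 in RIL60, 14.16 ± 0.48 in RIL78 and 12.99 ± 1.23 in RIL68. The well watered level of a116pe0012 was 10.34 ± 0.43 in RIL66, against 14.38 ± 0.32, 15.28 ± 0.30 and 13.64 ± 1.26 in RIL60, RIL78 and RIL68. Its stress level was 15.01 ± 0.48 in RIL66, against 12.64 ± 0.47, 15.42 ± 0.12 and 13.75 ± 1.17 in these lines. On replicate 2 of RIL68 the well watered levels, 11.09 and 11.81, were below those of the other 3 arrays of the line, which lay between 12.91 and 13.41 and between 13.84 and 14.53. The stress levels on that array, 14.80 and 15.42, were above those of the other 3. These lay between 12.14 and 12.70 and between 12.90 and 13.67. Levels between lines were not tested: no day in the file headers holds lines of both classes, and RIL66 shares a day with RIL68 on 1 array.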
